A study of Brassica juncea with 6 samples.

How the data were processed

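RNA from flowers was sequenced in 6 libraries, 3 of an apetalous nullisomic Brassica juncea line (AN) and 3 of its parent (YLC). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq kit. The deposited values are FPKM per gene and library, made by the authors, that is fragments scaled by gene length and library total, rounded to 2 decimals. HISAT2 is named in the submitters' processing notes without a version. The counting tool is not given in the sources used here. Of 98447 genes, 92888 had coordinates in the deposited annotation, 90046 of them on 18 chromosomes (10 of the A and 8 of the B subgenome) and 2842 on other scaffolds, and 5558 were assembled genes without coordinates. The 2 mean columns of the authors differed from the mean of the 3 libraries by at most 3.3e-05 and were not tested. Gene length in bases and gene coordinates, which are other deposited values, were used as given.

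Depth was inferred from the file. For genes of 450 to 900 bases with values under 0.6 FPKM, values were compared with whole multiples of 1 fragment (within 0.03 fragment plus rounding, up to 3.5 fragments). Between 84.8% and 89.0% came out whole, against 12.8% to 14.1% by chance, at 15400000 to 17700000 fragments per library. A gene at 1 FPKM therefore rests on few fragments in short genes, and a value of 0 is reported as listed at 0.

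Genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(FPKM + 1), with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a fold of at least 2. Tested on simulated data with the real means and spreads (55134 genes, 200 changed), the fit called 80% of genes changed by 1.2 on the log2 scale and 93% of those changed by 2, with 5 false calls. A list shifted by 0.5 was found, and 1 unshifted list was called. Gene lists (19, fixed before the data were examined) were tested with camera at a preset correlation of 0.01. Camera compares a list with the other genes, whereas fry, run besides it, asks whether the genes of a list changed at all. None of the 8 list calls held with an estimated correlation. The annotation holds no Arabidopsis locus codes, so list genes were matched through the best Swiss-Prot hit; 309 of 345 symbols matched. A best hit does not prove orthology, and members of a family can share one. Reads of near-identical copies in the A and B subgenomes may have been divided between them by the authors' counting, which makes single-copy values uncertain.

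Lost genes were those with a YLC mean of at least 1 FPKM and an AN mean under 0.1 of it, compared between chromosomes with a two-sided Fisher's exact test. A chromosome had an excess when its adjusted p was under 0.05 and its share above that of the other chromosomes. With positions shuffled, 0 chromosomes were called. Stretches of shifted expression were runs of at least 4 windows of 50 tested genes with a median log2 change (FPKM + 0.1) of at most -0.4, at most -3 or at least 0.4. They were chosen after seeing the data. Copies elsewhere were compared per Arabidopsis match with 100000 permutations, against matches with an expressed gene on the same chromosomes that was not lost. This comparison set was corrected once after a first result had been seen, since it had left out matches with a lost copy anywhere. All permutations were over genes or matches and not over libraries, so their p-values do not measure the spread between libraries. In 40 simulated draws of 300 against 600 independent values a shift of 0.3 was found in 85% and a shift of 0 in 5%. Shifts as small as those reported below, and sets of their size, were not simulated. GO and KEGG terms of 10 to 500 tested genes were tested with a hypergeometric test against the tested genes that carry any term. Computations outside R used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

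Named genes followed a rule fixed before the data were examined. It takes every tested copy of AP1, AP3, PI, AG, SEP1, SEP2, SEP3, PTL and RBE; the 8 higher and 8 lower called genes with the largest change among those with at least 10 FPKM in the higher group, no overlap between groups and a named protein, outside chromosomes with an excess of lost genes; the 5 lost genes with the highest YLC mean on each such chromosome; and up to 4 members of each list with the smallest p. Assembled genes without coordinates counted as outside these chromosomes, although their place is unknown. Names with words such as probable or putative were not counted as a named protein. The rule took 124 genes, of which the text prints a part; 1 gene of the auxin list is not reported here. Sums over copies and the copy counts of TCP4, BPE, SHP2, SHINE1, MYB16 and LOX2 were added after the values were seen. Alternatives were another pseudocount, other filters, TPM, median-ratio and quantile scaling, a replicate block, no trend, no minimum fold and leaving out each library. Count-based tests were planned only for deposited counts and were not applicable.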

Results

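Flowers of an apetalous nullisomic line of Brassica juncea (AN), obtained through interspecific hybridization, were compared by RNA sequencing with flowers of its parent line (YLC). Brassica juncea, the mustard crop, carries an A and a B subgenome, and a nullisomic plant lacks both copies of a chromosome. Each group held 3 libraries, and the deposited table gave FPKM values for 98447 genes. The depth was inferred from the size of the steps between low values, which corresponded to 15400000 fragments in AN replicate 1 and to between 17300000 and 17700000 in the other libraries. Between 50759 and 53389 genes reached 1 FPKM in each library. Pearson's r of the log2 values across genes, which are not independent replicates, was 0.973 to 0.984 within groups and 0.880 to 0.905 between groups. Gene values are mean FPKM ± SD (n = 3 libraries per group), and log2 fold changes (AN against YLC, on the log2(FPKM + 1) scale, which understates the change of low genes) are given ± SE with the adjusted p of limma. Nothing in the labels says that the libraries came from separate plants, so the p-values of limma measure only the spread between these samples, which may be technical.

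The first question was where in the genome expression was lost in the nullisomic. Chromosome A03 carried 981 lost genes among 3400 expressed in YLC (28.9%), lost meaning an AN mean under 0.1 of the YLC mean, against 2.80% on the remaining chromosomes. The loss was concentrated in the first part of the chromosome. Between positions 3208996 and 17011624 of A03, 760 of 854 expressed genes (89.0%) were lost, and the median log2 change of the 800 tested genes in that region was -5.52 (pseudocount 0.1), with AN libraries at -5.54, -5.52 and -5.53. Chromosome A04 was the only other chromosome past the threshold with a share above that of the rest, with 104 of 1581 genes lost (6.58%, adjusted p = 4.8e-04, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 chromosomes). Genes of a chromosome are not independent replicates, so these p-values describe the placement of genes. With A03 left out of the comparison chromosomes, a choice made after seeing the data, 5 chromosomes passed in this direction instead of 2, and 3 passed (A08 added) with lost meaning an AN mean under 0.25 of the YLC mean. Most other chromosomes differed in the other direction, with fewer lost genes than the rest, which include A03. With AN and YLC exchanged, as a background measured the same way, 5 chromosomes passed with a share above the rest (A01, A05, A09, B01 and B05), at shares of 2.83% to 3.65%.

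Lower and higher expression also extended over long stretches in which genes were still expressed. These stretches, runs of at least 4 consecutive windows of 50 tested genes, were defined after seeing the data. The next stretch of A03, from 17011883 to 38545775, had a median ratio of AN to YLC of 0.514 over 2450 tested genes. Of these genes 89.3% lay below 0 on the log2 scale. Positions of A03 before 3208996 and beyond 38545775 belonged to neither the silent nor the lowered stretch. On A08 the ratio was 0.530 between 2280667 and 13832605 and 0.556 between 20670544 and 24946891. Chromosome B03 stood at a ratio of 1.54 along both of its stretches, and the first part of A05, up to 8935342, at 1.81. A stretch of A06 had a ratio of 1.45 and the start of A04 one of 0.636, the latter with a wide spread between genes (quartiles -1.95 and 0.21). Over whole chromosomes the median log2 fold change was -1.02 for A03, -0.55 for A08 and 0.53 for B03. Without a filter on low values the medians were -0.32 for A08 and 0.37 for B03. In the 9 pairs of an AN with a YLC library the median of A08 ranged from -0.57 to -0.51 and that of B03 from 0.49 to 0.56, and the median of A03 was below 0 in all 9. Without YLC replicate 1, 2 or 3 the A03 median was -0.76, -0.74 and -0.75, and on the genes that pass with all 6 libraries -1.02, -1.01 and -1.04. All other regions had a median ratio of 1.04.

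**Figure D1:**
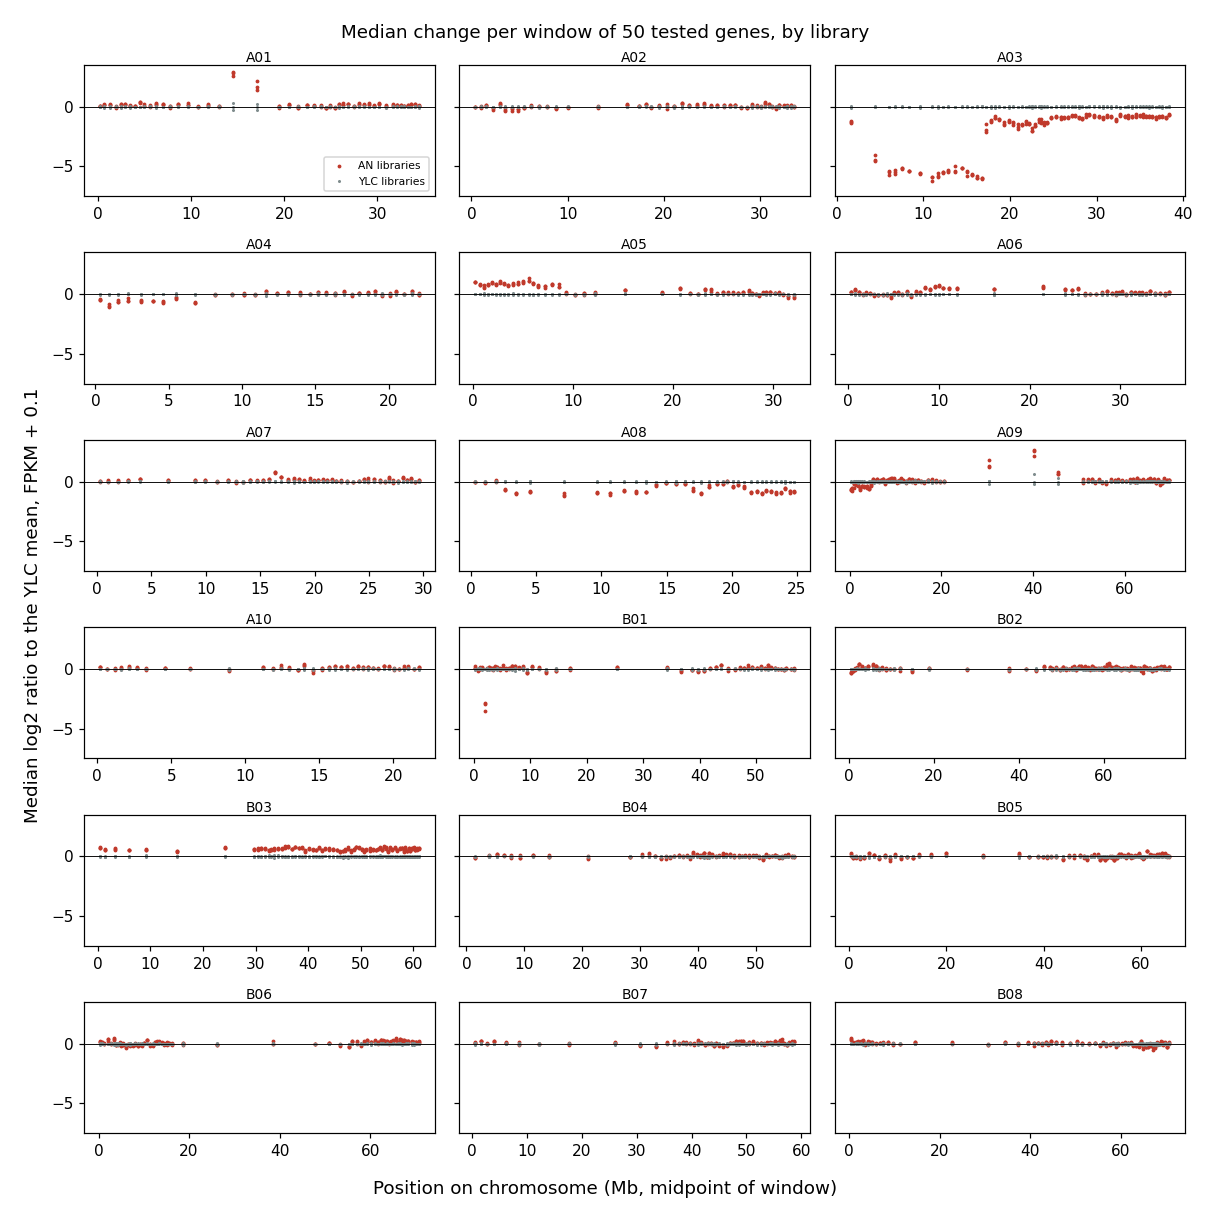
Median log2 ratio to the YLC mean (FPKM + 0.1) of each library in consecutive windows of 50 tested genes along the 18 chromosomes, against the window midpoint in Mb. Red points are the 3 AN libraries and grey points the 3 YLC libraries. The AN libraries lie near -5.5 between 3.21 and 17.0 Mb of A03 and below 0 from there to 38.55 Mb. They lie below 0 on most of A08, and above 0 along B03 and at the start of A05.

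Genes for floral organ identity were the next group of interest in an apetalous flower. Flowers were sequenced in bulk, so organ and stage content cannot be told apart from expression within an organ. That holds for these genes and for all lists below. Transcripts of the B-class genes APETALA3 (AP3) and PISTILLATA (PI), whose products specify petals and stamens, were lower in AN. Of 4 tested AP3 copies 3 fell, and of 5 PI copies 4 fell. The remaining AP3 copy (BjuA04g04640S, -0.92 ± 0.09, adjusted p = 3.9e-04) and PI copy (BjuB05g27180S, -0.50 ± 0.08, adjusted p = 0.0029) were lower but missed the fold threshold. That AP3 copy lies in the lowered stretch of A04, and the PI copy BjuA03g49420S in that of A03. The sum of AP3 copies was 256 ± 15 in AN and 680.4 ± 15.6 in YLC, and that of PI copies 200.3 ± 11.4 and 589 ± 48.2. The largest change of a PI copy was that on B08 (BjuB08g53000S, 66487403 to 66489680), at 27.5 ± 1.45 against 141 ± 12.5 (log2 fold change -2.32 ± 0.10, adjusted p = 9.0e-06), and the largest of an AP3 copy that on B08 (BjuB08g06230S), at 49.8 ± 7.62 against 157 ± 1.15 (-1.65 ± 0.12, adjusted p = 1.1e-04). The call of the AP3 copy BjuB06g02870S (-1.10 ± 0.08) was lost on the TPM scale, where its log2 fold change was -0.99. APETALA1 (AP1), which acts in sepal and petal identity, fell at 3 of 5 copies, of which the copy on A07 (BjuA07g30240S) lost its call without AN replicate 3. The 2 AP1 copies on B03, in its raised stretch, did not pass the fold threshold (-0.64 ± 0.20 and -0.56 ± 0.13). The 1 tested copy of SEPALLATA3, whose product is a cofactor of the other identity proteins, was at 44.8 ± 5.62 against 93.1 ± 2.05 (-1.05 ± 0.11, adjusted p = 4.1e-04), and that call was lost on the TPM scale and without AN replicate 3.

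The carpel and stamen gene AGAMOUS (AG) behaved differently between copies. Its copy on A03 (BjuA03g13910S, 14330974 to 14335834), inside the stretch with lost expression, was at 0.207 ± 0.126 in AN and 40.5 ± 1.24 in YLC (adjusted p = 8.1e-07). The remaining 4 copies did not pass the fold threshold, and the copy on A01 was at 57.9 ± 0.783 and 57.0 ± 3.86. The copy on B05 (BjuB05g48120S) was lower, at 63.5 ± 4.96 against 102 ± 4.55 (-0.68 ± 0.09, adjusted p = 0.0013). That on B02 was also lower (-0.76 ± 0.16, adjusted p = 0.0071), and that on B07 was higher (0.42 ± 0.12, adjusted p = 0.023). SEPALLATA1 fell at 1 of 4 copies, the one on A03, and no copy of SEPALLATA2 passed. PETAL LOSS and RABBIT EARS, regulators of petal initiation, had no tested copy. All 5 tested copies matched to SHATTERPROOF2, a carpel and fruit gene, rose, with a sum of 475 ± 61.1 against 137 ± 7.38. Among the 62 tested genes of the fixed organ identity list, 8 rose, 17 fell and 37 did not pass, with the same counts adjusted over the list alone. As a set they did not pass with camera (median -0.17, adjusted p = 0.289). They passed as lower with fry (adjusted p = 1.8e-04), which does not compare them with other genes. Of the 17 lower genes 5 lay in shifted stretches, and the median was 0.05 without those stretches, 0.07 without A03 and A04 and 0.05 without YLC replicate 3.

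**Figure D2:**
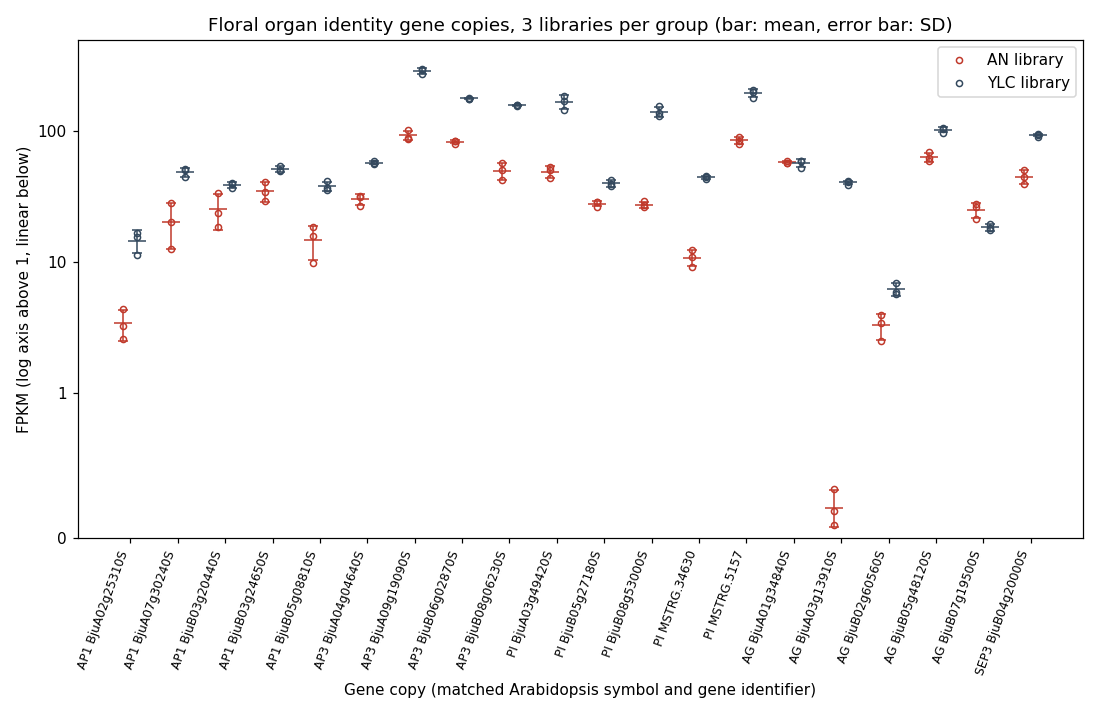
FPKM of each tested copy of AP1, AP3, PI, AG and SEP3 in the 3 AN libraries (red circles) and the 3 YLC libraries (blue circles), on a log axis above 1 and a linear one below, with the mean as a bar and the SD as error bar. The AP3 and PI copies lie lower in AN, and the AG copy of A03 lies at 0.207 in AN against 40.5 in YLC.

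Pollen genes had the lowest median log2 fold change of the 19 lists over all 6 libraries. Of 89 tested genes of the mature pollen list 65 fell and 0 rose (median -1.59, camera adjusted p = 4.6e-13, adjusted p = 0.487 with an estimated correlation). A copy of profilin-4 (MSTRG.6277), an actin-binding protein of pollen, was listed at 0 in all 3 AN libraries and at 188, 240.5 and 170.2 in the YLC libraries. The sum of the 3 tested profilin-4 copies was 39.3 ± 42.0 in AN, uneven between libraries, against 410 ± 80.1 in YLC. A copy of actin-depolymerizing factor 7 (BjuA03g10450S), in the silent part of A03, was at 0.163 ± 0.121 against 36.3 ± 5.92. The sum of its 6 tested copies was 27.9 ± 25.1 against 202 ± 27.5. AN replicate 1 stood apart from the other AN libraries for this list, with a median of -0.98 against -1.89 and -1.88. In contrast, the anther and tapetum list was divided, with 6 genes higher and 6 lower of 34 (adjusted p = 0.567). The tapetal gene A6 was higher on B03 (BjuB03g39280S, 42.1 ± 2.53 against 6.65 ± 0.621), while MALE STERILITY 2 on B01 was lower (0.510 ± 0.620 against 9.13 ± 1.25).

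Part of the genes for the petal surface and for carotenoid pigments fell, which in an apetalous line may reflect organ content. The cuticle and epidermis list had 23 genes lower and 1 higher of 55 (median -0.79, camera adjusted p = 1.2e-05, adjusted p = 0.487 with an estimated correlation). Examples were the cutin hydroxylase CYP86A4 on A09 (BjuA09g00320S, 1.55 ± 0.255 against 50.9 ± 5.34), the regulator SHINE1, of which 6 of 7 copies fell (sum 80.2 ± 22.4 against 335 ± 42.6), and MYB16, a regulator of conical epidermal cells, of which 3 of 5 copies fell (sum 49.8 ± 1.76 against 85.6 ± 4.53). Of 61 carotenoid genes 20 fell and 1 rose (median -0.50, adjusted p = 0.0018, adjusted p = 0.487 with an estimated correlation). Lycopene epsilon cyclase on B08 (BjuB08g50210S), which directs lycopene towards lutein, was at 14.9 ± 1.46 against 61.8 ± 4.89, and beta-carotene hydroxylase 2 on A10 and B02 was at 10.5 ± 1.22 and 6.99 ± 1.21 against 62.8 ± 4.17 and 46.8 ± 3.36. The list of petal initiation and growth as a whole did not pass (8 higher, 10 lower of 67, adjusted p = 0.427, median 0.17 and mean -0.02, which differ in sign). Its mean was 0.02, 0.09 and 0.06 without YLC replicate 1, 2 or 3, and -0.09, -0.08 and -0.10 without AN replicate 1, 2 or 3. In this list, all 5 TCP4 copies and both copies of BIGPETAL (BPE) fell. BPE, which limits petal cell expansion, was at 121 ± 9.50 against 522 ± 33.2 on A06.

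In 5 lists past the camera threshold the median was above 0, while most members did not pass the test of single genes. In the cell cycle list 15 genes rose and 4 fell of 59 (median 0.75, adjusted p = 1.2e-05, adjusted p = 0.487 with an estimated correlation), among them KNOLLE, a syntaxin of dividing cells, on B03 (27.5 ± 3.66 against 5.40 ± 0.717) and cyclin B1-2 on B08 (27.1 ± 2.82 against 6.29 ± 0.978). Of 57 auxin genes 8 rose and 4 fell (median 0.34, adjusted p = 0.0094, adjusted p = 0.487 with an estimated correlation), and IAA7, a repressor of auxin responses, was higher on A05 (47.6 ± 3.94 against 20.9 ± 1.82). In the photosynthesis list 11 genes rose and 3 fell of 76 (median 0.21, adjusted p = 0.016, adjusted p = 0.682 with an estimated correlation), with the chlorophyll-binding protein LHCB2.1 on B02 at 139 ± 17.1 against 24.1 ± 6.57. That call was lost with quantile normalization (adjusted p = 0.052) and without YLC replicate 1 or 3 (adjusted p = 0.080 and 0.102). Glucosinolate genes (13 higher, 5 lower of 44, median 0.53, adjusted p = 0.040, adjusted p = 0.487 with an estimated correlation) and flavonoid genes (6 higher, 3 lower of 30, median 0.48, adjusted p = 0.038, adjusted p = 0.541 with an estimated correlation) were close to the threshold. The flavonoid call was lost without AN replicate 1, 2 or 3 (adjusted p = 0.231, 0.218 and 0.077) and without YLC replicate 1 or 2 (adjusted p = 0.076 and 0.055). The flavonoid list also did not pass with fry (adjusted p = 0.076). The glucosinolate call was lost without AN replicate 1 or 2 (adjusted p = 0.221 and 0.082). Both were lost on the TPM scale (adjusted p = 0.057 and 0.059) and with quantile normalization (adjusted p = 0.052). In the glucosinolate list the A03 copy of GGP1, a glutamyl peptidase, was listed at 0 in the AN libraries and at 24.2, 26.6 and 28.4 in the YLC libraries.

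**Figure D3:**
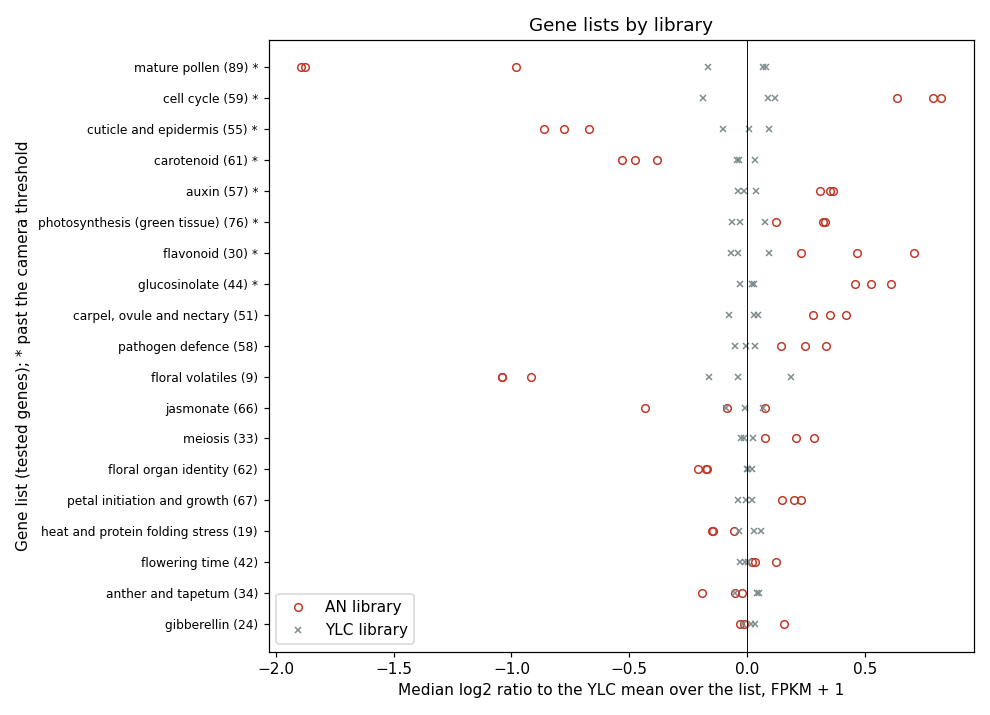
Median log2 ratio to the YLC mean (FPKM + 1) over the tested genes of each of the 19 lists, 1 point per library, with AN libraries as red circles and YLC libraries as grey crosses. Stars mark the 8 lists past the camera threshold. The mature pollen list lies at -0.98, -1.89 and -1.88 in the AN libraries, and in AN replicate 1 the floral volatiles list, at -1.04, lies below it.

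The other lists did not pass with camera. With fry, meiosis (adjusted p = 1.1e-04), carpel, ovule and nectary (1.9e-04) and flowering time genes (0.0043) passed as higher. Heat and protein folding stress (fry adjusted p = 1.8e-04) and floral volatiles (0.0046) passed as lower. Of 55134 tested genes 32321 had an unadjusted limma p under 0.05, so passing with fry does not set a list apart from other genes. The values below are those of camera. Meiosis genes had 8 higher and 1 lower of 33 (adjusted p = 0.280), with ASY1, a chromosome axis protein, on B03 at 7.03 ± 1.12 against 0.687 ± 0.0945. Carpel, ovule and nectary genes had 10 higher and 9 lower of 51 (adjusted p = 0.195), and flowering time genes 8 higher and 5 lower of 42 (adjusted p = 0.567, median -0.01 and mean 0.15, which differ in sign). The flowering time median was 0.08, 0.06 and 0.07 without YLC replicate 1, 2 or 3, and -0.08, -0.02 and -0.11 without AN replicate 1, 2 or 3. FLOWERING LOCUS T on A02 (BjuA02g27670S) was at 33.0 ± 1.44 against 3.46 ± 0.440. Jasmonate (6 higher, 12 lower of 66, adjusted p = 0.255), pathogen defence (8 higher, 7 lower of 58, adjusted p = 0.195), floral volatiles (1 higher, 4 lower of 9, adjusted p = 0.215, and past the threshold at 0.031 with the shifted stretches left out, a choice made after seeing the data), heat and protein folding stress (0 higher, 1 lower of 19, adjusted p = 0.427) and gibberellin genes (1 higher, 1 lower of 24, adjusted p = 0.691) completed the lists. Counts adjusted over the list alone were the same as over all genes in each list.

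Across the genome 4512 genes were higher and 7277 lower in AN among 55134 tested (limma, adjusted p under 0.05 and at least 2-fold). The libraries of the groups did not overlap for 34195 tested genes (62.0%, against 10% by chance). Of the lower genes 2254 lay in the shifted stretches, 751 of them in the silent part of A03, and of the higher genes 1043. The lower count was 4394, 4314 and 4590 without YLC replicate 1, 2 and 3. On the genes that pass with all 6 libraries it was 6904, 6805 and 7119. Among the named genes not placed on A03 or A04, the largest rises were those of Kunitz trypsin inhibitor 2 (MSTRG.4367, 261 ± 71 against 0.987 ± 0.221, log2 fold change 7.01 ± 0.19) and of an SHP2 copy (MSTRG.12123, 101 ± 18.4 against 0.150 ± 0.130, log2 fold change 6.46 ± 0.16). The genes annotated as phospholipid-transporting ATPase 6 (BjuA08g00920S, 0.880 ± 0.912 against 564 ± 209) and defensin-like protein 151 (MSTRG.669, 2.27 ± 3.52 against 676 ± 129) had the largest falls among them. The genes with MSTRG names have no coordinates, so their chromosome is unknown. On A04 a copy of the Rubisco small subunit (BjuA04g09510S, 9051051 to 9065337) was at 6.93 ± 1.44 against 3188 ± 256, whereas the sum of the 10 tested copies was 6743 ± 883 against 8148 ± 620.

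Functional terms were tested among the called genes. Among the lower genes 40 terms passed of 2204 tested (hypergeometric test, Benjamini-Hochberg adjustment), led by killing of cells of other organism (89 of 121 tested genes, adjusted p = 9.2e-52), by rejection of self pollen (61 of 126, adjusted p = 1.0e-20) and by polygalacturonase activity (39 of 106, adjusted p = 1.8e-08). Without the genes placed on A03 and A04, 38 terms passed. Among the higher genes 98 terms passed, led by apoplast (82 of 391, adjusted p = 6.7e-14), plant-type cell wall (43 of 158, adjusted p = 1.1e-10) and phenylpropanoid biosynthesis (56 of 275, adjusted p = 7.6e-09).

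Copies elsewhere of the genes lost on A03 and A04 were examined last. For 676 Arabidopsis matches with a lost gene on these chromosomes, the median log2 fold change of their copies on other chromosomes was -0.02, and 48.5% lay above 0. For 2350 matches with a gene that was not lost it was 0.11, and 60.2% lay above 0. The difference of -0.13 had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. With genes taken by their position in the silent part of A03, and not by their fall, the difference was -0.05 (two-sided permutation p = 0.052). These p-values come from permuting matches, which are not independent replicates, and do not measure the spread between libraries.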

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

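Tests chosen only after the result was seen are those with the shifted stretches left out, those on the same genes after leaving out a library, those with another comparison set for copies, and the comparison without A03. The counts of 4512 higher and 7277 lower genes stayed within 1.5 times with the pseudocount of 0.1, no filter, the TPM scale, median-ratio and quantile scaling and no trend. They were 3006 and 4665 with a filter of 5 FPKM, where fewer genes were tested, and 14720 and 14240 without a minimum fold. Leaving out a library gave 3259 to 4573 higher and 4314 to 7831 lower genes, and 4277 to 4586 and 6805 to 7836 on the same genes; the lowest counts (4394, 4314 and 4590 without YLC replicate 1, 2 and 3) come with 51616 to 51699 genes tested instead of 55134. Without the genes placed in shifted stretches 3469 were higher and 5023 lower. Same-numbered libraries did not deviate together (correlations 0.012, -0.019 and 0.026), which gives no sign of pairing. The labels do not say whether the numbers pair them. With the replicate block 4534 genes were higher and 7264 lower, and 8 lists passed. Chromosomes with an excess of lost genes numbered 2 without any 1 library, 3 (A08 added) with an AN mean under 0.25 of the YLC mean and 5 with A03 left out of the comparison. Of 8 lists past the threshold, 0 passed with an estimated correlation and 5 with quantile normalization. With fry, which does not compare a list with other genes, the photosynthesis and flavonoid lists did not pass. Several lists not called by camera passed with fry, organ identity among them. With the shifted stretches left out 9 passed, the floral volatiles added. With the pseudocount of 0.1, the TPM scale and median-ratio scaling, the median of A03 was -1.26, -0.93 and -1.07, that of A08 -0.66, -0.46 and -0.60, and that of B03 0.62, 0.60 and 0.48; without a filter, where 77077 genes were tested, they were -0.70, -0.32 and 0.37, with a filter of 5 FPKM -1.18, -0.64 and 0.60, and with quantile normalization -0.92, -0.45 and 0.61; without 1 library they ranged from -1.07 to -0.74, from -0.56 to -0.49 and from 0.50 to 0.54. The A03 median on the same genes ranged from -1.04 to -0.99, so its change without a YLC library comes with the filter. With median-ratio scaling the medians of A02, B01, B04, B05, B07 and B08, all between 0.017 and 0.045, were -0.0022, -0.0043, -0.010, -0.028, -0.0055 and -0.021, and that of A04, -0.03, was 0.058 on the TPM scale. Terms among higher genes numbered 98, and 151 without a minimum fold. The difference for copies ranged from -0.15 to -0.10. Of 124 named genes 0 reversed. Where no reason is given, the cause was not tested. Planned tests on counts were not run, since the values are FPKM.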

Other observations

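Copies of jasmonate genes went different ways, and their list did not pass (6 higher, 12 lower of 66). Of 8 tested copies matched to LOX2, a lipoxygenase of jasmonate synthesis, 4 rose, and the copy on B03 (BjuB03g24060S) was at 51.1 ± 4.61 against 1.99 ± 1.00 (SD, n = 3), but the sum of the 8 copies was 893 ± 88.5 against 944 ± 117. Vegetative storage protein 2 on B04 was at 127 ± 22.7 against 17.0 ± 2.03. Among the functional terms of the higher genes were cellular response to phosphate starvation (25 of 79, adjusted p = 1.5e-07) and endopeptidase inhibitor activity (16 of 28, adjusted p = 8.3e-09). Of the assembled genes without coordinates that were expressed in YLC, 898 of 4643 were lost in AN (19.3%, against 4.63% on chromosomes), and of those expressed in AN 374 of 4037 were lost in YLC (9.26%, against 1.99%). On unplaced scaffolds 34 of 651 genes were lost in AN (5.22%) and 157 of 846 in YLC (18.6%).

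Tests chosen only after the result was seen are that of single AN libraries, those of copies within each raised stretch, those of pollen genes without the shifted stretches or taken by the mean of all libraries, and the splits of the libraries. The 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 4512 higher and 7277 lower genes and the highest other split 1 gene, and for lists 8 against 6, so that 1 split of 10 was as large for each.

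Long stretches of A03 and A08 stood near 0.5 of the YLC level and B03 near 1.5. Genes of constitutive pathways, such as the ribosome, shared the shifts. Their median in the lowered stretches of A03 and A08 lay 0.97 below that of such genes elsewhere (-0.967, 237 against 2356 genes, permutation p = 1e-05, the smallest possible). On B03 it lay 0.559 above that of such genes elsewhere. The constitutive genes were among those by which the stretches were chosen, so these values cannot decide on a different organ content of the flowers. Genes of a stretch are not independent, so this p-value describes only the placement of genes. A single library is argued against by the AN library nearest to 0, at 0.609. Changed copy number of these segments may fit the ratios, and differing sequence of the hybrid parent stays open; neither was tested, since no DNA data were used here. Copies of genes of the silent part of A03 did not lie in raised stretches more often overall (-0.709 percentage points, permutation p = 0.28). By stretch they were less frequent on A05 (-2.91, permutation p = 1e-05). They were more frequent on A06 (0.308% against 0.115%, difference 0.193, permutation p = 0.021) and B03 (5.32% against 3.31%, difference 2.01, permutation p = 0.00051). The shares on A06 and B03 are low, and B03 was raised along both of its stretches. Such shares cannot show an exchange with the silent part of A03, which was not tested and stays open. For A05 the other A03 genes had the larger share of copies there (3.13% against 0.220%), so that an exchange with the rest of A03 stays open.

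Copies elsewhere of lost genes were lower than copies of other genes. With genes chosen by position in the silent part of A03, and not by their fall, the difference was -0.0528 (permutation p = 0.052), which leaves open whether the selection of genes by their fall accounts for it: that cannot be told apart here. For higher expression of the remaining copies a rise of more than 0.1 had been set as the prediction. Outside the shifted stretches the difference was -0.0375 (permutation p = 0.13), so copies of silent-part genes did not rise above copies of other A03 genes. Those other genes lay largely in the stretch of A03 at a ratio of 0.514. A rise of copies in both sets would cancel, so the test cannot decide whether remaining copies rose.

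Mature pollen genes were lower, and AN replicate 1 less so than the other AN libraries. Their placement in shifted stretches is argued against by a median of -1.52 without those genes. A lower share of pollen in the AN libraries, lower expression in each grain and a different stage of the flowers cannot be told apart, since each predicts a fall: 98.3% of the 59 list genes at 10 FPKM or more in YLC lay below 0, as did 98.1% of 54 taken by the mean of all libraries. The log2 fold changes of the latter were not alike (quartiles -2.81 and -1.05).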
